A study of Homo sapiens with 9 samples.

How the data were processed

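RNA was measured in MDA-MB-231 cells, a human breast cancer line, after transfection with a control siRNA or with 1 of 2 siRNAs against SET7, the lysine methyltransferase encoded by SETD7. The 9 libraries fall into 3 groups of 3. Control libraries carry the numbers 1, 5 and 6 in their titles, siRNA A libraries 2, 7 and 8, and siRNA B libraries 3, 4 and 9. The labels do not say what the numbers mark, nor whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

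Per the labels' protocols, libraries were prepared from total RNA with a Lexogen kit and sequenced on a SOLiD instrument. Reads were counted per gene symbol with HTSeq on the hg19 build, per the submitters' processing notes. The aligner, the gene annotation, the strand setting and the versions are not given in the sources used here. The deposited values are raw read counts, 1 library per file, with no normalization by the authors. The 5 summary entries that HTSeq adds were kept out of library sizes and tests. Of gene counts and these 5 entries together, reads outside genes made up 8.85 to 10.9% and ambiguous reads 0.383 to 0.498%. Reads without a unique position came to 39.4 to 42.4% of the same total in 8 libraries and to 49.1% in control library 6. A table of the whole series held the same counts, with 0 differing values, and spelled 15 symbols differently (as dates).

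Gene counts totalled 15689751 to 24388135 per library. No 2 replicate libraries agreed within sampling noise. The squared deviation between 2 replicates over its Poisson variance had a median over genes of at least 1.78, which sampling noise alone would not reach. Reads from near-identical copies, such as histone genes and ribosomal protein genes with pseudogenes, are discarded or split by such counting, and without a stated strand setting reads from overlapping antisense genes cannot be told apart, so the values of these genes are uncertain.

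Of 23368 genes, 2096 had no count and 13254 passed filterByExpr (min.count 10) in edgeR 4.0.16 (R 4.3.3). Differences were tested on the counts with edgeR's quasi-likelihood test (TMM factors, robust, 1 mean per group, 6 residual degrees of freedom over all 9 libraries) with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of single genes come from this test throughout. The comparisons were siRNA A against control, siRNA B against control, the mean of both siRNAs against control, and siRNA A against siRNA B. Levels are CPM (counts scaled to library size, edgeR cpm) of the deposited counts with TMM factors. SETD7 was also compared by a two-sided exact permutation test of log2 CPM.

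Before the data were examined, 25 gene lists, the design, most alternatives and the rule for named genes were fixed. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, then with an estimated correlation and with fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes. The list of mitochondrially encoded genes had no tested member. The rule named SETD7, then for each siRNA the 10 genes with the largest rise and the 10 with the largest fall among those with adjusted p under 0.05, at least 10 CPM on average and no overlap between siRNA and control libraries. It took 10 per direction for both siRNAs, ranked by the smaller change, 5 per direction for siRNA A against siRNA B, and up to 4 members of a list. Some genes that the rule picks are not reported here.

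Transcript GC content, 3′ UTRs and coding sequences were taken from GENCODE release 29. By symbol 20194 genes matched, a further 1480 matched through a RefSeq synonym and 1694 did not match; 96.2% of tested genes had a GC value. GENCODE 29 describes another build than hg19, so no coordinates are given. A GC correction (a loess curve per library, span 0.3, of log2 deviation on GC content, used as offsets) was added after the data were seen. So were the same correction with control library 6 left out, the removal of genes with a 3′ UTR motif, and a scan of 16237 7-base motifs over the 3′ UTRs of 12290 tested genes, each motif present in at least 50 genes.

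The alternatives fixed beforehand were DESeq2 size factors or total counts in place of TMM, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma voom, only the 2 groups compared, a term for library numbers 1 to 3 against the others, an adjusted p under 0.01, a log2 fold change of at least 1, the table of the whole series, and leaving out each library in turn.

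The methods were tested on simulated data. With 200 changed genes in siRNA A against control, over 13090 genes, edgeR recovered 6.06% of genes changed 1.5-fold, 62.7% at 2-fold and 97.0% at 4-fold, and 5.98% of its calls were unchanged genes. Unchanged genes made up 18.1% of the calls of DESeq2, over 13254 genes, and 5.31% of those of limma voom. With the libraries' GC curves and no changed gene, edgeR called 0 of 13121 genes for siRNA A, 1 for siRNA B and 0 for both. Of 20 unchanged lists, camera called 0. Their genes were simulated independently, while the estimated correlation among G2/M genes was 0.18, so this does not cover lists of correlated genes. A motif effect planted at -0.3 was estimated as -0.31.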

Results

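Gene expression was profiled in MDA-MB-231 cells, a mesenchymal-like breast cancer line, in 3 libraries each of cells given a control siRNA, SET7 siRNA A or SET7 siRNA B. The series asks how repression of SET7 changes the transcriptome. Control libraries 1, 5 and 6 held 17531706, 20684843 and 24388135 gene counts. The siRNA A libraries 2, 7 and 8 held 16234660, 16211627 and 16624910, and the siRNA B libraries 3, 4 and 9 held 18738399, 18102589 and 15689751.

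SETD7, the gene encoding SET7, was reduced in all 6 libraries given a SET7 siRNA. The control libraries 1, 5 and 6 had 68.4, 60.4 and 60.1 CPM of SETD7 (mean 63.0 ± 4.70, SD, n = 3). With siRNA A the level was 9.43 ± 0.975 CPM (SD, n = 3), 15% of control, and with siRNA B it was 8.24 ± 1.19 CPM (SD, n = 3), 13% of control. The log2 fold changes were -2.74 ± 0.17 (SE, adjusted p = 2.1e-05) and -2.93 ± 0.17 (SE, adjusted p = 8.0e-06). A two-sided exact permutation test gave p = 0.1 for each, the smallest p that 3 libraries against 3 allow. SETD7 differed between the siRNAs by 0.19 on the log2 scale, within the replicate spread (adjusted p = 0.47; exact permutation p = 0.2).

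**Figure D1:**
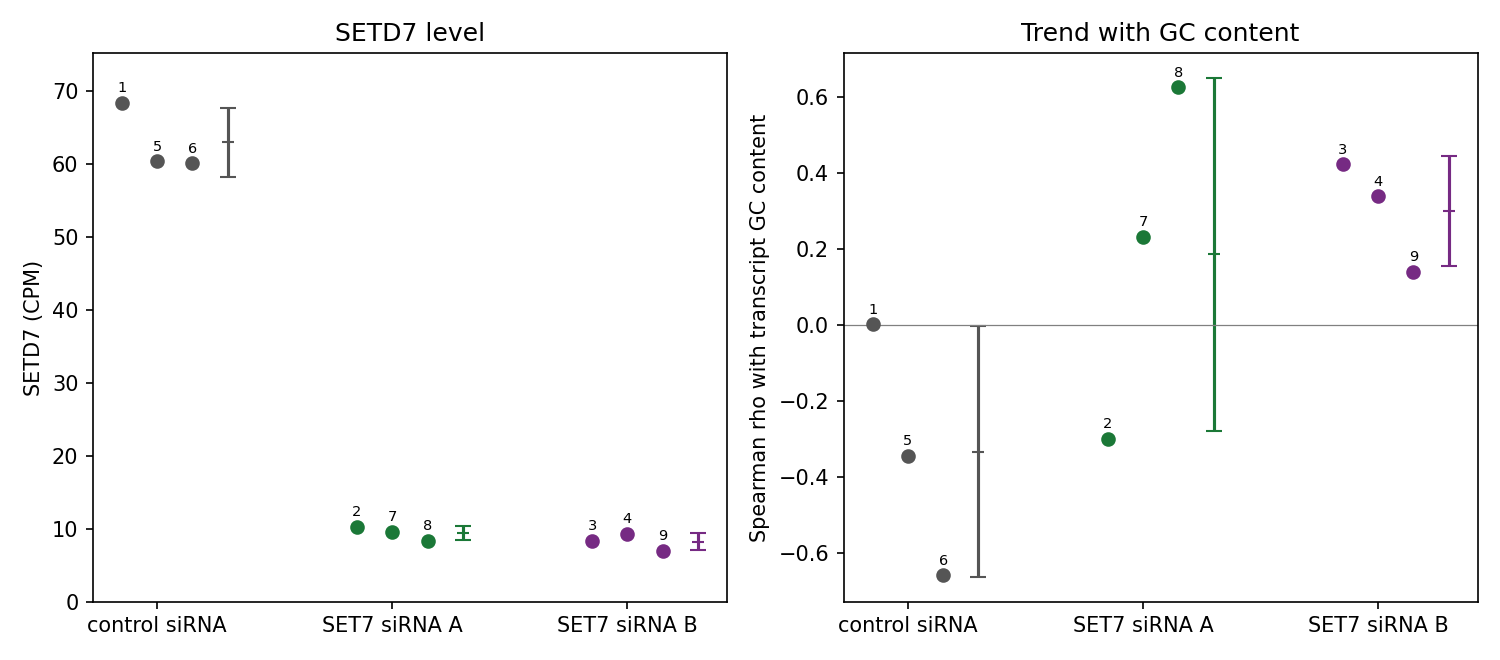
SETD7 in CPM (left) and the Spearman correlation of each library's log2 deviation with transcript GC content (right), 1 point per library with its number, bars giving mean ± SD of 3. SETD7 was 60.1 to 68.4 CPM in control libraries and at most 10.3 CPM with either SET7 siRNA, while the GC correlation ran from -0.66 in control library 6 to 0.63 in siRNA A library 8.

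The libraries also differed along GC content. The correlation of a library's deviation with GC content across genes, which are not independent replicates, was 0.00, -0.34 and -0.66 in control libraries 1, 5 and 6. It was -0.30, 0.23 and 0.63 in siRNA A libraries 2, 7 and 8, and 0.42, 0.34 and 0.14 in siRNA B libraries 3, 4 and 9. Fold changes against control rose with GC content (Pearson r across genes 0.47 with siRNA A and 0.45 with siRNA B), and those of siRNA A against siRNA B did not (-0.05). Control library 6 stood apart on the first principal component (48.4% of variance, score -77.0). It differed from the other control libraries by a root mean square of 0.646 on the log2 scale, against 0.242 to 0.488 for the other 8 libraries from their own replicates. The second component (24.3%) separated siRNA A from siRNA B.

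Genes that rose with both siRNAs included a collagen, a metalloproteinase inhibitor and a pair of receptors. COL7A1, the anchoring-fibril collagen VII, rose from 2.06 ± 0.543 CPM to 20.8 ± 4.11 with siRNA A and 19.9 ± 2.55 with siRNA B (SD, n = 3). Its log2 fold changes were 3.35 ± 0.24 (SE, adjusted p = 2.7e-05) and 3.28 ± 0.24 (SE, adjusted p = 2.9e-05). TIMP3, a metalloproteinase inhibitor, rose from 46.4 ± 0.204 CPM to 227 ± 8.56 and 209 ± 8.55 (SD, n = 3). The pseudokinase TRIB2 (2.41 with siRNA A and 2.44 with siRNA B), complement C3 (2.22 and 2.10) and APCDD1L (2.18 and 2.13) rose on the log2 scale. TMEM87B (2.15 and 1.96), GPR124 (2.08 and 2.26), and the collagen receptor DDR1 (1.97 and 1.90) followed on the log2 scale. The growth factor receptor PDGFRB rose from 3.27 ± 0.974 CPM to 13 ± 0.806 and 17.8 ± 2.41 (SD, n = 3). Adjusted p was 5.5e-04 or lower in each comparison for each of these genes.

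After SETD7, the genes lower with both siRNAs that ranked first were TAF1D (log2 fold change -1.92 with siRNA A and -2.02 with siRNA B), the transcribed pseudogene SFTA1P (-1.87 and -1.75), TFPI, the inhibitor of tissue factor (-2.51 and -1.68) and SYF2 (-1.66 and -1.75). They were followed by the spindle gene SKA1 (-1.65 and -2.20), BORA (-1.80 and -1.65), TGDS (-1.98 and -1.65) and VEPH1 (-1.69 and -1.64). MYEF2 fell from 40.4 ± 15.9 CPM to 13 ± 2.22 and 10.1 ± 0.265 (SD, n = 3). Several owed much of their size to control library 6. TFPI stood at 161 and 230 CPM in control libraries 1 and 5 and at 603 in control library 6, and without that library its log2 fold changes were -1.75 and -0.92. Without it TAF1D changed by -0.76 and -0.86, SKA1 by -0.66 and -1.21, BORA by -1.09 and -0.95, TGDS by -1.26 and -0.93, and SYF2 by -0.48 (adjusted p = 0.096, no longer past the threshold) and -0.57. Leaving out 1 siRNA library ended calls too, but moved the log2 fold changes little. TAF1D lost its call with siRNA A without siRNA A library 7 or 8 (-1.90 and -1.86, adjusted p = 0.084 and 0.087) and with siRNA B without siRNA B library 3 or 4 (-2.03 and -1.90, adjusted p = 0.052 and 0.063). SKA1 lost its call with siRNA A without siRNA A library 2, 7 or 8 (-1.70, -1.73 and -1.54, adjusted p = 0.057, 0.077 and 0.099). SYF2 lost its call with siRNA A without any 1 of the 6 siRNA libraries (-1.73 to -1.57, adjusted p = 0.060 to 0.13) or after GC correction (adjusted p = 0.051). With siRNA B it lost its call without siRNA B library 3, 4 or 9 (-1.74, -1.79 and -1.72, adjusted p = 0.082, 0.078 and 0.076). SFTA1P kept -1.48 and -1.36 and VEPH1 -1.43 and -1.39 without control library 6.

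In all, 995 genes were higher and 702 lower past the threshold with both siRNAs, out of 13254 tested, and 315 and 180 of these changed at least 2-fold with each. Independent lists of these sizes would share 263.0 and 244.3. Another 69 genes passed in opposite directions, and 211 did after GC correction. Of the 1697 genes called in 1 direction, 1368 (813 higher, 555 lower) were called the same way with each siRNA after GC correction. The number was 1529 without control library 6 and 919 when only the 2 groups compared were fitted. It was 2863 without control library 1, with the balance turned round (1333 higher, 1530 lower), and it fell to 841 without siRNA A library 7 and to 987, 984 and 1095 without siRNA B libraries 3, 4 and 9.

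The fold changes of the siRNAs correlated across genes (Pearson r = 0.674, Spearman rho = 0.678), where genes are not independent replicates, and 76.2% had the same sign. When all groups, controls included, were simulated as unchanged, r was 0.489, 66.4% had the same sign and 0 genes were called with both, over 50 simulations. The simulated controls held neither the GC curves nor a library that stood apart, so these values may be too low for the data. The covariance was 0.297 against a simulated 0.034, and 0.203 after GC correction. As 3 control libraries cannot be divided into sets of at least 2, part of the excess over these values may come from the shared controls.

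**Figure D2:**
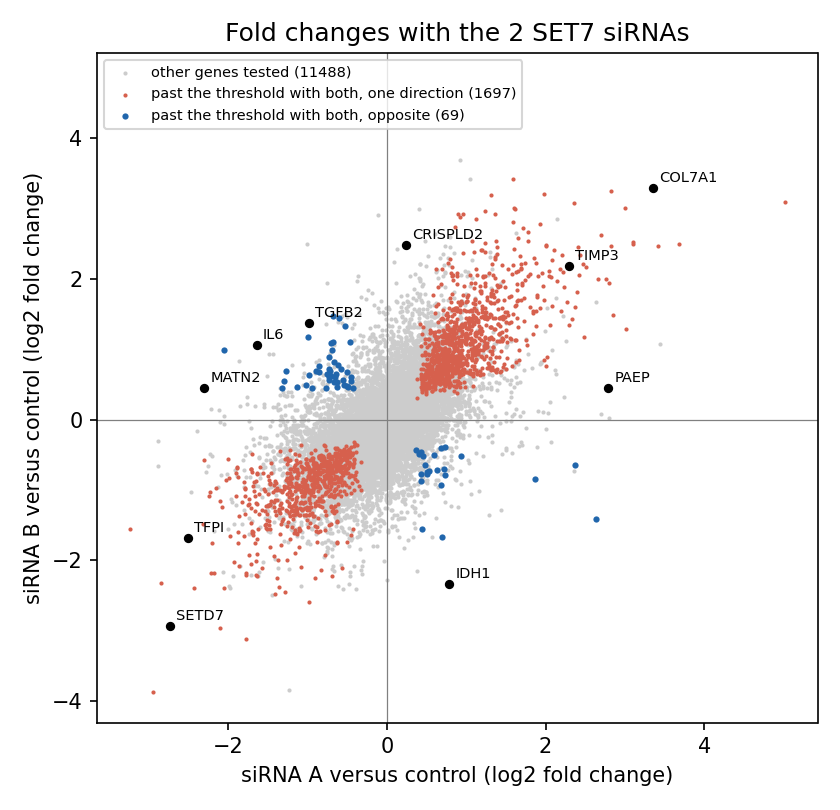
Log2 fold change against control with siRNA A (x axis) and siRNA B (y axis), 1 point per gene tested, red for the 1697 genes past the threshold with both in 1 direction, blue for the 69 in opposite directions, black for some named genes. COL7A1 and TIMP3 lie high with both, SETD7 and TFPI low with both, and IDH1, IL6 and TGFB2 lie on opposite sides of 0.

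Among the gene lists, mesenchymal and TGF-beta/SMAD target genes were higher and stress response and G2/M genes lower in the mean of both siRNAs against control. Of 31 mesenchymal genes tested, 17 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 2.5e-05; adjusted p = 0.16 with an estimated correlation). COL5A1 (log2 fold change 1.64 ± 0.16, SE), COL6A1 (1.24 ± 0.15) and the transcription factor SNAI2 (1.68 ± 0.19) rose, while the collagenase MMP1 fell (-1.87 ± 0.19). Of 28 TGF-beta/SMAD target genes, 15 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 4.1e-05; adjusted p = 0.16 with an estimated correlation). Among the risers were IL11 (1.81 ± 0.17), PMEPA1 (2.02 ± 0.20) and LTBP1 (1.18 ± 0.13). These 2 lists have 9 tested members each that another list also holds. Their median GC content was 53.9% and 54.7%, above the 48.8% of all genes tested, and both kept their call after GC correction (camera adjusted p = 1.2e-04 and 2.8e-04).

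Of 6 fibroblast markers tested, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 6.8e-04; adjusted p = 0.16 with an estimated correlation). Among the risers were PDGFRB (2.23 ± 0.21), S100A4 (1.70 ± 0.26) and COL1A1 (1.29 ± 0.23), with 3 of the 6 shared with other lists. Of 19 Wnt/beta-catenin target genes, 11 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0019; adjusted p = 0.22 with an estimated correlation). The Notch ligand JAG1 changed by 1.16 ± 0.15 and BMP4 by 0.92 ± 0.13 (0.40 with siRNA A, adjusted p = 0.067, and 1.44 with siRNA B). With siRNA A alone the Wnt list did not pass (camera adjusted p = 0.061). Of 37 hypoxia target genes, 10 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0052; adjusted p = 0.16 with an estimated correlation). The carbonic anhydrase CA12 changed by 1.39 ± 0.14 and PFKFB4 by 1.51 ± 0.21. With siRNA B alone the hypoxia list did not pass (camera adjusted p = 0.075).

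Unfolded protein and integrated stress response genes were lower: 19 of 35 fell and 3 rose (20 and 3 adjusted over the list alone; camera adjusted p = 2.6e-04; adjusted p = 0.16 with an estimated correlation). Asparagine synthetase ASNS changed by -1.05 ± 0.12, CTH by -0.98 ± 0.12, the chaperone DNAJC3 by -0.88 ± 0.12 (-0.19 with siRNA A, adjusted p = 0.33, and -1.56 with siRNA B) and the transcription factor XBP1 by -0.76 ± 0.12. Of 40 G2/M genes, 19 fell and 2 rose (23 and 3 adjusted over the list alone; camera adjusted p = 6.8e-04; adjusted p = 0.32 with an estimated correlation). HMMR changed by -1.35 ± 0.18 and TOP2A by -1.19 ± 0.22 (-0.58 with siRNA B, adjusted p = 0.10). With siRNA B alone the G2/M list did not pass (4 lower, 5 higher; 3 and 3 adjusted over the list alone; camera adjusted p = 0.36), and CDCA3 (1.19 ± 0.17), KIF20A (0.72 ± 0.15) and CENPA (0.68 ± 0.15) rose. The median GC content of G2/M genes was 43.2%, and after GC correction their median moved from -0.42 to -0.27 and 16 fell (camera adjusted p = 0.0029). Of 19 replication-dependent histone genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.20 with an estimated correlation). Examples are HIST1H1E (-0.74 ± 0.14) and HIST1H3B (-1.30 ± 0.26). Of 76 cytosolic ribosomal protein genes, 17 fell and 0 rose, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.33 with an estimated correlation). RPS23 changed by -0.75 ± 0.16 (-0.09 with siRNA A, adjusted p = 0.76, and -1.42 with siRNA B) and RPS4X by -0.71 ± 0.18. With siRNA A alone the ribosomal protein list did not pass (camera adjusted p = 0.093), with 1 of 76 lower and 0 higher (0 and 0 adjusted over the list alone).

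NF-kB target genes (13 of 29 higher, 4 lower; 15 and 5 adjusted over the list alone) and NRF2 target genes (9 of 30 higher, 2 lower; 9 and 2 adjusted over the list alone) were just past the threshold (camera adjusted p = 0.045 each; adjusted p = 0.16 with an estimated correlation each). The adhesion molecule ICAM1 rose (0.92 ± 0.11) and NFKB1, a subunit of the factor itself, fell (-0.74 ± 0.11; -0.21 with siRNA A, adjusted p = 0.26, and -1.28 with siRNA B). The catalase gene CAT rose (0.84 ± 0.10) while the cystine transporter SLC7A11 fell (-0.95 ± 0.16). With siRNA A alone neither list passed (camera adjusted p = 0.13 each). In the mean of both siRNAs the camera adjusted p after GC correction was 0.064 for NF-kB and 0.15 for NRF2 target genes. Both calls also ended without control library 1 (0.094 and 0.066), siRNA A library 7 (0.050 each) or siRNA B library 9 (0.058 and 0.059). The NF-kB call also ended without siRNA A library 8 (0.054), and the NRF2 call without control library 6 (0.069) or siRNA A library 2 (0.050).

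The remaining lists against the mean of both siRNAs did not pass. For genes encoding reported SET7 protein substrates, 3 of 25 were higher and 4 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.95). EPAS1 rose with siRNA B (1.13) and not past the threshold with siRNA A (-0.04, adjusted p = 0.84). For cholesterol synthesis genes 7 of 26 were higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.052), and for lysosome and autophagy genes 12 of 36 were higher and 3 lower (13 and 3; 0.079). Oxidative phosphorylation genes had 1 of 54 higher and 9 lower (0 and 0; 0.20), G1/S target genes 5 of 43 higher and 11 lower (5 and 11; 0.24), and immune cell markers 2 of 4 higher and 0 lower (2 and 0; 0.10). Epithelial genes had 7 of 28 higher and 2 lower (7 and 2; 0.20) and interferon response genes 4 of 38 higher and 3 lower (2 and 2; 0.68).

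**Figure D3:**
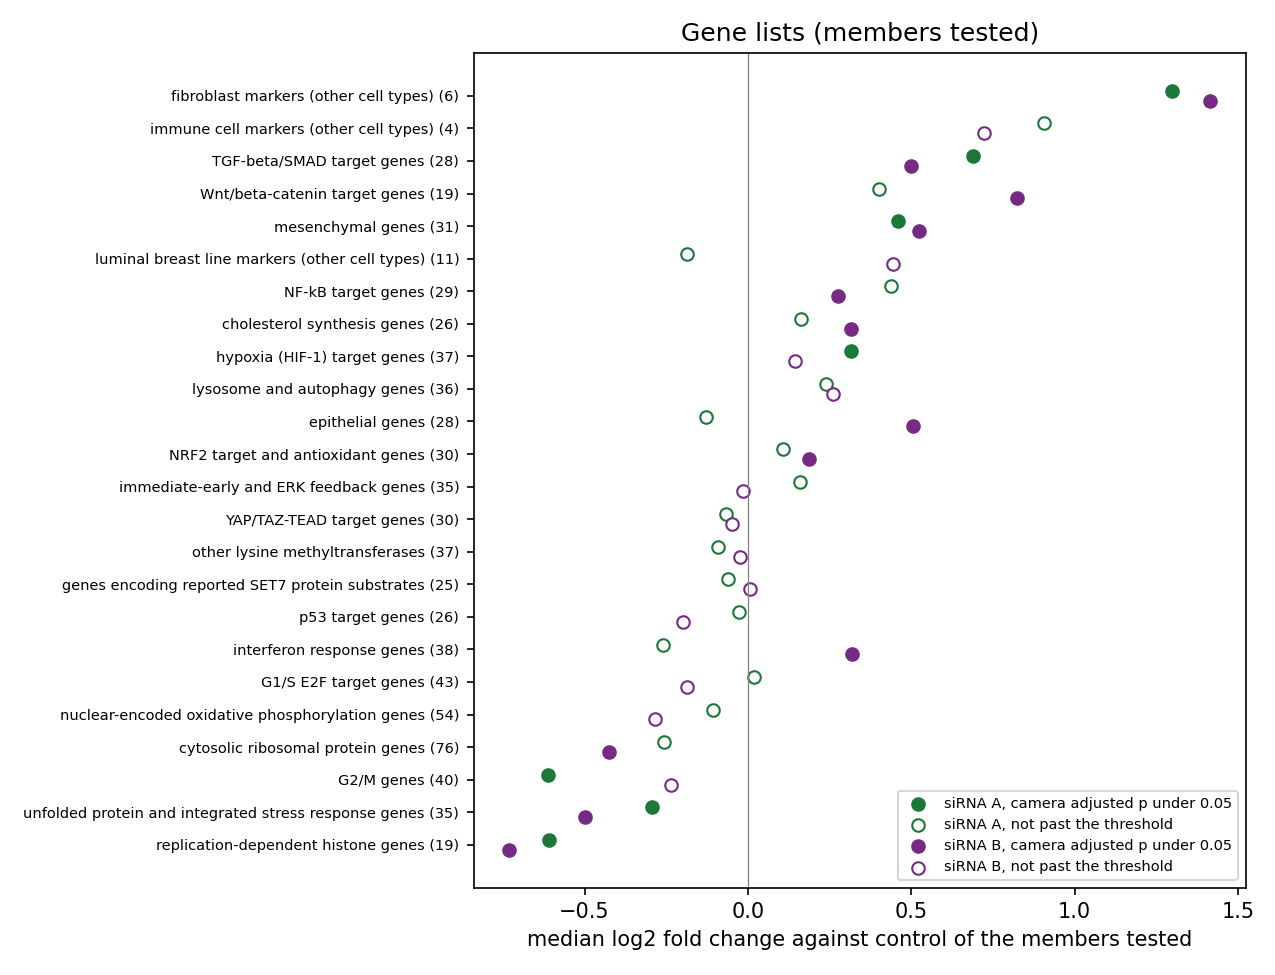
Median log2 fold change against control of the tested members of each list (number in parentheses) with siRNA A (green) and siRNA B (purple), filled where the camera adjusted p was under 0.05. Histone, stress response and mesenchymal genes lie on the same side of 0 with both siRNAs, while epithelial and interferon response genes lie on opposite sides.

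With siRNA A alone the highest-ranked genes included several that siRNA B did not raise past the threshold. PAEP, which encodes glycodelin, rose from 12.8 ± 2.80 to 88.5 ± 12.4 CPM (SD, n = 3; log2 fold change 2.79 ± 0.20, SE, adjusted p = 2.7e-05), against 0.44 with siRNA B (adjusted p = 0.091). STC1, which encodes stanniocalcin, rose by 2.24 ± 0.16 (0.32 with siRNA B, adjusted p = 0.13), and SEMA7A by 2.33 ± 0.19 (1.43 with siRNA B). Among genes that met the naming rule (at least 10 CPM, no overlap), the largest falls after SETD7 and TFPI were in SLC25A15, a mitochondrial ornithine carrier (-2.30 ± 0.15), MATN2 (-2.30 ± 0.19), GCC2 (-2.23 ± 0.34), FOPNL (-2.23 ± 0.30), RAI14 (-2.16 ± 0.26), PPA1 (-2.13 ± 0.41), and EIF2S3, a subunit of translation factor eIF2 (-2.02 ± 0.22). CELF2 fell from 52.0 ± 14.3 to 13 ± 1.63 CPM (SD, n = 3). Each of these had an adjusted p of 0.0050 or lower.

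G2/M genes fell with siRNA A: 22 of 40 were lower and 0 higher (30 and 0 adjusted over the list alone; camera adjusted p = 1.7e-08; adjusted p = 0.20 with an estimated correlation). Among them were HMMR at -1.80 ± 0.22, TOP2A at -1.81 ± 0.27 and KIF2C at -0.57 ± 0.11. Hypoxia targets were higher (10 of 37, 1 lower; 10 and 1 adjusted over the list alone; camera adjusted p = 5.6e-04; adjusted p = 0.20 with an estimated correlation). They included NDRG1 at 0.88 ± 0.12 and EGLN3 at 1.76 ± 0.24. Mesenchymal (15 of 31 higher, 1 lower), TGF-beta/SMAD (15 of 28 higher, 2 lower), fibroblast (5 of 6 higher, 0 lower), stress response (13 of 35 lower, 1 higher) and histone (6 of 19 lower, 0 higher) lists also passed (camera adjusted p from 9.9e-05 to 0.0015). The 7 lists had adjusted p from 0.196 to 0.224 with an estimated correlation. Adjusted over the list alone, higher and lower counts were 15 and 3 for mesenchymal, 17 and 5 for TGF-beta/SMAD, 5 and 0 for fibroblast, 1 and 14 for stress response and 0 and 10 for histone genes.

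Against control, 1591 genes were higher and 1486 lower with siRNA A (549 and 568 at least 2-fold), and 2663 of the 3077 (86.5%) were called after GC correction too. The median GC content was 56.0% for higher and 43.0% for lower genes, against 48.8% for all tested. Without control library 1 more genes were lower (2346) than higher (2072). The count was 2955 without control library 6, 1430 without siRNA A library 7, 1906 without siRNA A library 8, and 1545 when only these 2 groups were fitted.

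With siRNA B, besides COL7A1, genes with large rises included OLFML2A (log2 fold change 2.96 ± 0.22, SE; 14.3 ± 4.17 to 111 ± 12.3 CPM, SD, n = 3), PTGES, a prostaglandin E synthase (2.92 ± 0.19), GPRC5B (2.87 ± 0.22), LOXL4, a lysyl oxidase (2.73 ± 0.24), and the pro-apoptotic gene BMF (2.53 ± 0.18). PLSCR4 (2.53 ± 0.15) and CRISPLD2 (2.48 ± 0.15) followed, all of these with adjusted p of 4.9e-05 or lower. TMEM192 (-2.58 ± 0.25), GMFB (-2.47 ± 0.39), RAB3IP (-2.45 ± 0.24), MCTS1 (-2.40 ± 0.29), EIF2S1, another subunit of eIF2 (-2.40 ± 0.21), MMP1 (-2.37 ± 0.25), VBP1 (-2.37 ± 0.45) and ATP5J2 (-2.34 ± 0.54) fell, with adjusted p of 0.0083 or lower. Without control library 6 the falls were -1.85 for GMFB, -1.63 for VBP1 and -1.5 for ATP5J2. LY96 (-2.36 ± 0.70, adjusted p = 0.025) rested on control library 6, with 259 CPM there and 28.7 and 37.7 in control libraries 1 and 5. Without that library its change was -0.65 (adjusted p = 0.077), and it also lost its call without siRNA B library 3, 4 or 9, at changes of -2.35, -2.17 and -2.56 (adjusted p = 0.079, 0.095 and 0.054).

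Mesenchymal (17 of 31 higher, 1 lower; camera adjusted p = 7.4e-05) and TGF-beta/SMAD target genes (13 of 28 higher, 1 lower; camera adjusted p = 7.4e-05) led the lists with siRNA B, with COL5A1 at 2.04 ± 0.18 and SNAI2 at 1.88 ± 0.20. With an estimated correlation 0 of the 12 lists that passed with siRNA B kept their call (adjusted p from 0.153 to 0.228). Of 28 epithelial genes 9 rose and 3 fell (camera adjusted p = 0.0027), with plakoglobin, encoded by JUP, at 1.43 ± 0.19 and the desmosomal PKP2 at -1.37 ± 0.20. Ribosomal protein genes (18 of 76 lower, 0 higher), stress response genes (17 of 35 lower, 2 higher), histone genes (4 of 19 lower, 0 higher) and Wnt targets (11 of 19 higher, 1 lower) passed as well. So did fibroblast markers (4 of 6 higher, 0 lower), cholesterol synthesis genes (6 of 26 higher, 0 lower), interferon response genes (10 of 38 higher, 2 lower), NF-kB targets (12 of 29 higher, 3 lower) and NRF2 targets (8 of 30 higher, 3 lower), these 9 lists with camera adjusted p from 2.6e-04 to 0.032. Adjusted over the list alone, higher and lower counts were 18 and 1 for mesenchymal, 14 and 1 for TGF-beta/SMAD, 9 and 3 for epithelial, 0 and 11 for ribosomal protein, 2 and 19 for stress response and 10 and 2 for interferon response genes. They were 0 and 2 for histone genes, 12 and 2 for Wnt targets, 4 and 0 for fibroblast markers, 5 and 0 for cholesterol synthesis genes, 12 and 3 for NF-kB targets and 8 and 3 for NRF2 targets. The NF-kB and NRF2 calls ended after GC correction (0.052 and 0.082) and without control library 1 (0.058 each), which also ended the interferon call (0.096).

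Against control, 2191 genes were higher and 2179 lower with siRNA B (923 and 743 at least 2-fold), and 3636 of the 4370 (83.2%) were called after GC correction too. The median GC content was 56.5% for higher and 43.6% for lower genes. The count was 4306 without control library 6, and 2502, 2487 and 2879 without siRNA B libraries 3, 4 and 9. For the mean of both siRNAs, 2184 genes were higher and 2433 lower, and 3519 of the 4617 (76.2%) were called after GC correction. Without control library 6, 3710 passed, with the balance turned round (1899 higher, 1811 lower). It also turned round with limma voom (2273 and 2146).

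The genes that differed most between the siRNAs included IDH1, IL6 and TGFB2. IDH1, a cytosolic isocitrate dehydrogenase, was 28.7 ± 1.72 CPM with siRNA A and 3.28 ± 0.602 with siRNA B (SD, n = 3), a log2 difference of 3.13 ± 0.19 (SE, adjusted p = 2.3e-05), with 16.6 ± 2.15 CPM in control. TSPO (2.53 ± 0.28), PAEP (2.35 ± 0.19), the peroxiredoxin PRDX2 (2.24 ± 0.20) and MCTS1 (2.01 ± 0.29) were also higher with siRNA A. MATN2 (-2.75 ± 0.19), the cytokine IL6 (-2.70 ± 0.31), TGFB2 (-2.35 ± 0.21), CRISPLD2 (-2.23 ± 0.15) and EIF4E3 (-2.11 ± 0.26) were lower. Against control IL6 fell with siRNA A (-1.64) and rose with siRNA B (1.06), as did TGFB2 (-0.98 and 1.37).

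G2/M genes were lower with siRNA A than with siRNA B (12 of 40 lower, 0 higher; 19 and 0 adjusted over the list alone; camera adjusted p = 1.4e-07; adjusted p = 0.30 with an estimated correlation). Examples are ANLN at -1.60 ± 0.24 and CDCA3 at -1.06 ± 0.17. Interferon response genes (11 of 38 lower, 2 higher; 17 and 3 adjusted over the list alone; camera adjusted p = 1.8e-05; adjusted p = 0.092 with an estimated correlation) included PARP14 (-1.11 ± 0.17) and SAMD9L (-2.70 ± 0.45). Epithelial genes (11 of 28 lower, 0 higher; 12 and 1 adjusted over the list alone; camera adjusted p = 7.6e-05; adjusted p = 0.092 with an estimated correlation) included the tight junction gene CLDN1 (-3.04 ± 0.31) and JUP (-1.37 ± 0.19). Wnt targets were lower (8 of 19, 1 higher; 8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.010; adjusted p = 0.36 with an estimated correlation), and BMP4 differed by -1.04 ± 0.15. G1/S targets were higher (7 of 43, 1 lower; 8 and 1 adjusted over the list alone; camera adjusted p = 0.036; adjusted p = 0.17 with an estimated correlation). So were ribosomal protein genes (4 of 76, 0 lower; 1 and 0 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.59 with an estimated correlation). The G1/S gene DSCC1 differed by 1.28 ± 0.26 and RPS23 by 1.33 ± 0.20.

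Between the siRNAs 1061 genes were higher and 1128 lower with siRNA A than with siRNA B, and 2168 of the 2189 (99.0%) were called after GC correction, which called 4070. The count was 4032 without control library 6, which enters this comparison through the spread shared by the groups, 1031 without siRNA A library 7, and 1042, 1158 and 1138 without siRNA B libraries 3, 4 and 9. Of 1311 genes called with siRNA A and not with siRNA B, 521 passed this comparison, as did 1020 of the 2604 called with siRNA B and not with siRNA A. The G1/S call ended without siRNA A library 2 (0.052) or siRNA B libraries 4 or 9 (0.061 and 0.058), and the ribosomal call without siRNA A library 8 (0.058) or siRNA B library 4 (0.061).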

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

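The tests of the 3′ UTR base composition were chosen only after the motifs had been seen; the other tests in this part were set out before their values were known. The genes and lists below differ between siRNA A and siRNA B by a direct test.

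Of 52 named genes, 29 differed between the siRNAs, but 10 of these were named for the size of this difference, which sets part of that share. Of all 13254 genes tested, 2189 differed. The 12 higher with siRNA A, with the log2 difference of siRNA A from siRNA B, were IDH1 (3.13), TSPO (2.53), PAEP (2.35), PRDX2 (2.24), MCTS1 (2.01), STC1 (1.91), ATP5J2 (1.86), EIF2S1 (1.85), TMEM192 (1.60), RAB3IP (1.17), MMP1 (1.01) and SEMA7A (0.90). The 17 lower with siRNA A were MATN2 (-2.75), IL6 (-2.70), TGFB2 (-2.35), CRISPLD2 (-2.23), EIF4E3 (-2.11), PTGES (-2.02), GPRC5B (-1.95), LOXL4 (-1.88), FOPNL (-1.74), SLC25A15 (-1.72), OLFML2A (-1.71), BMF (-1.46), CELF2 (-1.43), RAI14 (-1.19), EIF2S3 (-1.17), GCC2 (-1.16) and PLSCR4 (-0.74). The calls of 3 of these genes ended without single libraries, at differences in the same direction. GCC2 lost its call without siRNA A library 7 or 8 or siRNA B library 3, 4 or 9 (adjusted p = 0.12, 0.12, 0.084, 0.074 and 0.13), with log2 differences of -1.25 to -0.97. ATP5J2 lost it without the same libraries (0.076, 0.13, 0.080, 0.14 and 0.091; differences of 1.39 to 2.07), with no filter (0.14) and with a term for library numbers (0.058). MMP1 lost it without siRNA A library 2 or 7 or siRNA B library 3 or 4 (0.058, 0.058, 0.077 and 0.074), with differences of 0.84 to 1.03.

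The lists that differed were G2/M genes (camera adjusted p = 1.41e-07), interferon response genes (1.80e-05), epithelial genes (7.61e-05), Wnt/beta-catenin targets (0.0101), ribosomal protein genes (0.0113) and G1/S targets (0.0356). With an estimated correlation 0 of the 6 passed (adjusted p = 0.30, 0.092, 0.092, 0.36, 0.59 and 0.17). In addition, 69 genes passed the threshold against control in opposite directions with the siRNAs. Of these, 24 were higher with siRNA A and 45 higher with siRNA B. All 69 also passed the direct comparison, but opposite changes add up there, so this is no separate support. After GC correction 211 genes passed in opposite directions.

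Genes lower with a SET7 siRNA more often held a 7-base 3′ UTR motif, which differed between the siRNAs. For each siRNA the motif with the most negative z (effect over its standard error) of the 16237 scanned was picked. The z was -18.9 with siRNA A and -16.0 with siRNA B. Over 100 scans of permuted siRNA A fold changes the largest absolute z was 4.85. The z, the SE and these scans treat genes as independent replicates and do not measure the spread between libraries. GAAGTAA went with a log2 change of -0.32 ± 0.02 (SE, 1577 genes) with siRNA A and -0.05 with siRNA B, and GCTGAAT with -0.30 ± 0.02 (SE, 1506 genes) with siRNA B and -0.01 with siRNA A. GAAGTAA was in 12.8% of all genes searched, 34.2% of those lower with siRNA A, 28.5% of those lower with both siRNAs, and 49.3% of the 349 lower with siRNA A than both control and siRNA B. For GCTGAAT and siRNA B the shares were 12.3%, 26.2%, 23.8% and 40.0% (of 552). As the motifs were picked on these same fold changes, the shares describe the pattern and are no separate support for it. Base composition is argued against, as the effects were 0.989 and 0.989 times as large with base and dinucleotide shares of the 3′ UTR as covariates.

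Repression of unintended transcripts through the siRNA seed may explain part of the falls. Of the genes named above for falls with siRNA A, TFPI, MATN2, GCC2, FOPNL, PPA1, EIF2S3 and CELF2 held GAAGTAA in the 3′ UTR. SLC25A15 and RAI14 did not. With siRNA B, TMEM192, GMFB, RAB3IP, MCTS1, EIF2S1, VBP1 and ATP5J2 held GCTGAAT, MMP1 did not, and LY96 was not searched. Of those lower with both, MYEF2 and BORA held both motifs, TFPI only GAAGTAA and SKA1 only GCTGAAT. TAF1D, SYF2, TGDS and VEPH1 held neither, and SFTA1P was not searched. Of the genes named for being higher with siRNA A than with siRNA B, IDH1, TSPO, PRDX2 and MCTS1 held GCTGAAT and PAEP did not. Of those named for being lower, TGFB2, EIF4E3 and MATN2 held GAAGTAA, and IL6 and CRISPLD2 did not. MATN2 also held GCTGAAT. For siRNA B the 3′ UTR effect was 3.12 times the coding effect, as seed repression predicts. For siRNA A, 2 or more sites went with -0.47 and 1 site with -0.29 (difference -0.18 ± 0.04, SE), which also goes with seed repression. Genes with a site followed by A changed by -0.42 and other carriers by -0.24 (difference -0.18 ± 0.03, SE). For the same motif, GAAGTAA, in the siRNA B fold changes this difference was 0.01 ± 0.03 (SE). For GCTGAAT with siRNA B, genes with a site followed by A changed by -0.45 and other carriers by -0.25 (difference -0.20 ± 0.04, SE). No outcome had been set out for a following A. For GCTGAAT with siRNA B, 2 or more sites went with -0.48 and 1 site with -0.27 (difference -0.21 ± 0.05, SE). With siRNA A the 3′ UTR effect of GAAGTAA was only 1.24 times its coding effect. This is short of the 2 times set out beforehand, so the question stays open for siRNA A. The coding effect was fitted with the length and GC content of the 3′ UTR, not of the coding sequence, which limits this ratio. SETD7 itself holds 1 coding copy of each motif, the outcome set out beforehand for a target site, but 34.2% and 36.7% of 1773 transcripts of like length hold it too, so this decides nothing; that stricter reading was adopted after the value was seen. The siRNA sequences are not given in the sources used here. A biological difference between the siRNAs, such as an unequal loss of SET7 protein, was not tested.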

How the results depend on the processing

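The GC correction, the same correction without control library 6, and the removal of genes with the control motif were chosen only after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the groups share no library numbers. No fold change of SETD7 or of a called named gene, and no called list, changed direction. The balance of higher and lower genes did in some settings, for example: without control library 1 it was 1333 higher and 1530 lower with both siRNAs (995 and 702 with all libraries) and 2072 and 2346 with siRNA A (1591 and 1486), and DESeq2 gave 1806 and 1969 with siRNA A. Where counts changed, the cause was not tested unless stated.

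SETD7 kept its call with each siRNA under the alternatives that test it (its 3′ UTR holds the control motif, so the removal of such genes leaves it out), at -2.81 to -2.66 with siRNA A and -3.03 to -2.81 with siRNA B when single libraries were left out. DESeq2 called 3775 genes with siRNA A, 4856 with siRNA B and 2116 with both, limma voom 3022, 4268 and 1657, and a term for library numbers 2504, 3792 and 1350. In simulated data 18.1% of the calls of DESeq2 for siRNA A were unchanged genes, against 5.98% with edgeR. Scaling by total counts or DESeq2 size factors moved the median of all genes by at most 0.01.

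By construction, stricter thresholds called fewer genes. At an adjusted p under 0.01 the counts were 1241 with siRNA A, 2067 with siRNA B, 578 with both, 2045 for the mean and 933 for siRNA A against siRNA B. With a log2 fold change of at least 1 they were 1117, 1666, 495, 1203 and 802. With only the 2 groups compared they were 1545 with siRNA A, 919 with both and 3685 for siRNA A against siRNA B. GC correction gave 4070 for siRNA A against siRNA B, and 5730 with control library 6 left out as well. Leaving out genes with the control motif, and so testing fewer, gave 2013 with siRNA A.

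Leaving out 1 library gave 1430 (without siRNA A library 7) to 4418 (without control library 1) genes with siRNA A, 2487 (without siRNA B library 4) to 5482 (without control library 1) with siRNA B, and 841 (without siRNA A library 7) to 2863 (without control library 1) with both. For the mean the range was 3226 to 5707, and for siRNA A against siRNA B 1031 (without siRNA A library 7) to 4032 (without control library 6). Groups left with 2 libraries used the spread pooled over the 3 groups.

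The correlation of the siRNAs' fold changes moved from 0.674 to 0.526 with no filter on low counts, 0.586 after GC correction, 0.531 after GC correction without control library 6, and 0.567 (without control library 6) to 0.741 (without control library 1) when single libraries were left out.

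With an estimated correlation 0 lists passed in each comparison, against 7 with siRNA A, 12 with siRNA B, 11 for the mean and 6 for siRNA A against siRNA B. With fry, which asks another question, 16, 19, 17 and 10 passed. Leaving out 1 library gave 7 to 9, 10 to 14, 9 to 12 and 4 to 6.

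Of 399 results for named genes, 362 kept their call under each of 11 alternatives that could test them. Genes named for both siRNAs entered this tally by the mean of both. The loss of the SYF2 call with siRNA A after GC correction is thus not in it. Of 446 calls, 378 were kept without each of the 9 libraries in turn. LY96 with siRNA B also lost its call with no filter (adjusted p = 0.13), limma voom (0.080) and only the 2 groups compared (0.063). In the self-test, where 200 genes changed, 6.06% of 1.5-fold changes were recovered. With so few changed genes the adjusted threshold is stricter than in the data, so this share does not carry over.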

Other observations

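The tests of GC content in single libraries, of GC content as the whole cause, of a SET7 siRNA library under a control label, and of base composition were chosen only after the results were seen; the other tests in this part were set out before their values were known.

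Several regulators moved although their lists did not pass in the mean of both siRNAs. Of 26 p53 targets, 3 rose and 9 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.39), with TP53INP1 at 1.31 ± 0.17 (SE; 0.42 with siRNA A, adjusted p = 0.13, and 2.21 with siRNA B) and the cell cycle inhibitor CDKN1A at -0.88 ± 0.16. Of 30 YAP/TAZ-TEAD targets, 4 rose and 7 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.68), and the matricellular genes CTGF (-0.72 ± 0.11) and CYR61 (-0.66 ± 0.12; -0.26 with siRNA A, adjusted p = 0.18, and -1.06 with siRNA B) fell. Of 37 other lysine methyltransferases, 1 rose and 7 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.43), with EHMT2 at 0.78 ± 0.15 and the Polycomb enzyme EZH2 at -0.82 ± 0.14. Of 35 immediate-early and ERK feedback genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.24), with the phosphatases DUSP4 at 0.81 ± 0.12 and DUSP1 at -0.78 ± 0.09. Of 11 luminal breast line markers, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.73), with FOXA1 at -0.78 ± 0.14.

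The trend of fold changes with GC content may come from bias of single libraries: the widest range of the GC correlation within a group was 1.46 times the widest difference between group means. Such bias is argued against as the whole cause of the genes called with both siRNAs, as 80.6% were called the same way after GC correction. Control library 6 held SETD7 at 0.934 times the mean of the other control libraries, which argues against a SET7 siRNA library under a control label. After GC correction it still deviated by 0.510, 1.28 times the highest of the other 8 libraries (0.399 in control library 1). The value of control library 1 is itself measured in part from control library 6, and the highest siRNA library had 0.337 (siRNA A library 2). Among 3 marker lists of other cell types the highest median difference was 0.147 (4 immune markers, control median 0.589 CPM). GC bias and RNA from other cells stay open. No biological explanation was tested for a single library.

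The motif picked for the largest positive z in the mean of both siRNAs was TACATTT (z = 12.2). Genes with it in the 3′ UTR were higher with both SET7 siRNAs by 0.16 ± 0.01 on the log2 scale (SE, 3289 genes). Here too, z and SE are across genes and do not measure the spread between libraries. Base composition (with base and dinucleotide shares as covariates the effect was 0.975 times as large) and control library 6 (the effect without it was 0.976 times that with it) are argued against. Seed repression by the control siRNA in the control libraries may contribute, as the 3′ UTR effect was 7.52 times the coding effect. That coding effect was about as large as its standard error (0.02 ± 0.02), so the size of the ratio is uncertain. It was -0.01 with siRNA A and 0.05 with siRNA B. Genes with 2 or more sites were higher than genes with 1 (difference 0.14 ± 0.02, SE, mean of both siRNAs). Loss of SET7 stays open, since the siRNAs differed by only -0.012 in this effect and both explanations predict a value near 0. The motif was in 27.9% of genes higher with both siRNAs, 32.3% of those lower with both and 26.8% of all genes searched. It thus does not mark the higher genes as a set. Among genes with a searched 3′ UTR, 644 of 967 higher and 288 of 656 lower genes held none of the 3 motifs, against 7551 of all 12290. Carriers of a motif were thus more frequent among genes lower with both, but the motifs were picked on these same fold changes.

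Other groupings of the libraries were fitted in the same way. For siRNA A, siRNA B and siRNA A against siRNA B the real groupings gave 1545, 3993 and 3685 genes when only the 2 groups were fitted, the highest other split gave 0, and 1 of 10 splits, the real one, gave as many, which is too few splits for a share under 0.05. For the mean of both siRNAs the real grouping gave 4617 genes, the highest other 2712, and 1 of 100 splits, the real one, gave as many. Other splits mix libraries of different groups, which widens their spread, so the real grouping was likely to lead. The splits show that the count goes with these labels. They cannot exclude chance differences between the groups, as the libraries of a group may not be separate cultures. For genes called with both siRNAs the values were 1697, 679 and 1 of 100, with the same limit. In each of these, the highest other split kept the real control libraries and mixed the siRNAs, and splits with other control libraries reached at most 1586 and 538.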
